A study of Streptomyces natalensis ATCC 27448 with 18 samples.

How the data were processed

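Transcript levels were measured in mycelium of Streptomyces natalensis ATCC 27448 and of its mutants CAM.02, which lacks sodF (ΔsodF), and CAM.04, which lacks ahpCD (ΔahpCD). Each strain was sampled in late exponential phase (T1) and in early stationary phase (T2), with 3 biological replicates per strain and phase and 1 array per replicate, 18 arrays in all. Per the labels' protocols, total RNA was purified on columns, copied into cDNA and labelled with Cy3, and genomic DNA of the wild type was labelled with Cy5 and hybridised to every array as a common reference. Dyes were not swapped, so a dye effect of a probe is the same on all 18 arrays and drops out of differences between groups. Groups and replicate numbers were taken from the sample titles.

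Per the file headers, the deposited files hold the spot intensities of 1 array each, extracted with Agilent Feature Extraction 9.5.1.1. The columns used were the mean intensity of each spot and the median intensity of its local background in both channels, which the authors deposited without further correction. Agilent's processed intensities, which per the file headers were background-subtracted, detrended and dye-normalised by the scanner software, were used as an alternative. That dye normalisation ran over all spots, the pimaricin tiles included, so it may take up part of a shift of the cluster, which was not tested. The spot flags for outliers, saturation and signal well above background were used as deposited. A further deposited table of normalised values has 18 value columns whose headings match no sample label, and it was not used here.

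The arrays hold 8606 spots of gene probes, 3236 tiles over the pimaricin region, 3236 mismatch copies of those tiles with 5 changed bases each, 130 spots of mismatch copies of named probes and 536 control spots. Both channels were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, on all spots. Control spots and outlier spots were then left out. The 130 mismatch copies of named probes were left out of the features, a choice made after the files were seen. The log2 ratio of Cy3 over Cy5 was centred on each array's median over gene probes and normalised between arrays by cyclic loess (3 iterations, span 0.7) fitted on gene probes, with the tiles carried along at weight 0. Centring on the gene probes assumes that the median probe did not change. A probe was kept where Cy3 was well above background on at least 3 of the 18 arrays, spots of a probe and probes of a gene name were averaged on the log2 scale, and 4700 of 7819 features (60.1%) remained. Within a comparison 4692 to 4700 of them had values in every group.

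Most features are named by identifiers of the form SAV or SCO plus a number (4493 and 51 tested). The files do not pair these identifiers with gene names and no gene table or genome was used here, so at most 2 that rose and 2 that fell are given per comparison. Symbols with the prefix sna_ (33 tested) carry the names of Streptomyces natalensis genes, 28 tested features carry symbols of other species, and 95 belong to clusters of other polyenes. In the Cy5 channel, where every array received the same genomic DNA, 46.4% to 87.7% of SAV probes and 100% of sna_ probes were well above background, so a SAV value stands for whatever natalensis sequence that probe captured. The precision is limited by the 3 arrays per group.

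The tile sequences were assembled into a region of 93992 bp with no conflicting base, and coding frames were predicted with prodigal 2.6.3. Positions are counted from 1 at the start of that region, since no genome build was used. The mean of the tiles in each frame, or in the span of the probes of sna_pim_03 and sna_pim_04, which had no frame on their strand, was tested in the same model as the features.

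All 18 arrays entered 1 limma model of 6 group means with moderated variances (lmFit and eBayes), and 11 contrasts were tested. Features were called at a Benjamini-Hochberg adjusted p under 0.05 within the contrast. Gene lists fixed beforehand were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Of the 17 lists, those for the pimaricin cluster (22 features), the phosphate regulon (9 features) and morphological development (1 feature, ssp_nsdA, called in no comparison) had members on the array. The other 14 lists had none: antioxidant enzymes, redox regulators, thiol redox, iron and siderophores, other metal transport, ribosomal proteins, respiration and ATP synthase, central carbon metabolism, acyl-CoA precursor supply, other secondary metabolism, nitrogen assimilation, heat shock and proteolysis, DNA repair, and sulfur and cysteine metabolism. The symbol match of the pimaricin and phosphate lists was widened to the array's own naming after the names were seen. The 9 phosphate features are probes for phoP, phoR and phoU of natalensis and for phoP and phoR of other species, so several read the same transcript and they are not independent. Features were named by a rule: called, with the same sign in each replicate, the largest changes among those with a symbol, up to 3 called members per list, and any member of the pimaricin cluster. The uncalled features outside the cluster that are given with their values were chosen after those values were seen.

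Per the file headers, replicate number, slide and scan coincide: each of the 3 slides held 1 array of every group, and a group had the same position on every slide, so position and group cannot be told apart. Deviations from the group means were correlated above 0.1 in 43 of 45 pairs of arrays with the same number (median r 0.699, lowest 0.071), against a median of -0.469 over the 90 pairs with different numbers. Deviations cancel within a group, so the negative median follows from the positive one. The number is also that of the biological replicate, so an effect of the slide cannot be told apart from a batch of cultures or RNA. It is called the slide here, and a fit with the slide as a fixed block was set beside each result whose call it changed. It was not the planned first fit, which has group means only.

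Tested on simulated data for ΔsodF against wild type at T1 (4495 features, 200 changed, 5 runs), the fit without a block recovered 21.5%, 78.5% and 90.0% of features changed by 1, 2 and 3 log2 units with 0% false calls. With the block it recovered 66.0%, 97.0% and 99.4% with 5% false calls. A list of 22 members shifted by -1 was called in 5 of 5 runs and an unshifted list in 0. The simulated features were drawn independently around additive slide effects, a setting that favours the block. In the data the estimated correlation was 0.699 within the pimaricin list and 0.514 within the phosphate list. These runs therefore do not show how camera at the preset correlation behaves for lists whose members move together.

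The alternatives fixed before the data were examined covered normalisation (median centring only, quantile, loess within each array, Cy3 alone), background (none, Cy3 only, Agilent's processed signals), the filter on dim probes, the brightest probe per gene, the slide as a block, fits on the groups of a contrast alone, a trended robust variance, a 2-fold threshold and each array left out in turn. A further 6 were added after seeing the data: normalisation on gene probes and tiles together, normalisation on probes with Cy5 well above background on all arrays, a filter on the same criterion, the mismatch copies kept as features, the fit without slide 2, and, for the covariance of the mutants, an expected value from differences within slides. Arrays were left out after normalisation. Of a feature not well above background on any array of a group only a bound is known there. This was examined for natalensis symbols, selected symbols of other species and the identifiers named below, but not for the other tested features. It held for 3 symbols of other species, none of them named singly below, though the lysA features among them enter the lysA list.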

Results

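The transcriptomes of wild-type Streptomyces natalensis, an actinomycete that makes the polyene antifungal pimaricin (natamycin), and of its ΔsodF and ΔahpCD mutants were compared at 2 points of growth, in a series about the control of reactive oxygen species and the making of pimaricin. The gene sodF encodes an iron superoxide dismutase, which turns superoxide into hydrogen peroxide and oxygen, and ahpCD encodes an alkyl hydroperoxide reductase system, which removes peroxides. Cultures grew at 30 °C and 250 rpm in baffled flasks of YEME, a yeast and malt extract medium. There were 6 groups of 3 arrays, and every value is a normalised log2 ratio of Cy3 (cDNA) over Cy5 (wild-type genomic DNA). No probe carried the name sodF, ahpC, ahpD or oxyR or that of a resistance cassette, so the deletions were not checked by name.

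The median Cy3 signal of gene probes lay between 90.8 and 116 per array over a median local background of 43.5 to 46.5, and 35.4% to 59.99% of gene probes were well above background. The median Cy3 signal of the tiles was 738 to 16320, with at least 99.97% of tiles well above background. Arrays of a slide resembled each other: the first principal component held 57.1% of the variance, and slide accounted for 77.8% of it. In the Cy5 channel the median log2 ratio of tiles to their mismatch copies was highest on slide 2 in 6 of 6 groups, by 0.53 to 0.85 over the mean of slides 1 and 3.

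**Figure D1:**
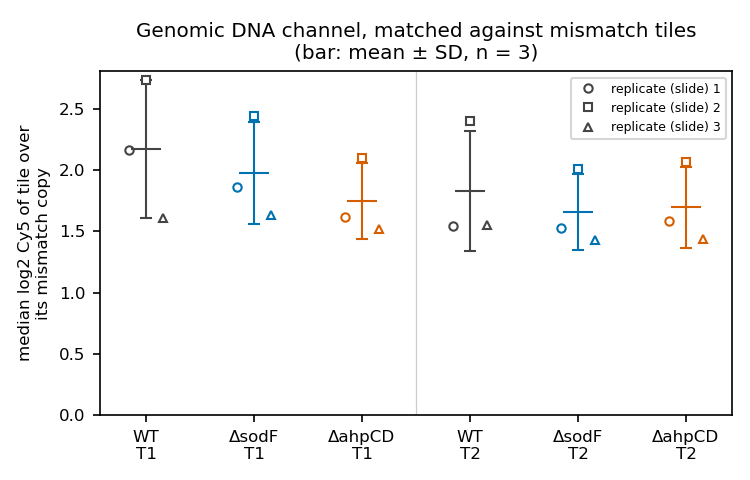
Median log2 ratio of the Cy5 (genomic DNA) signal of pimaricin tiles to that of their mismatch copies, 1 point per array (18 arrays), with bars for the group mean ± SD (n = 3). In each of the 6 groups the square, slide 2, is the highest point.

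The pimaricin genes are tiled over 93992 bp and carry the names sna_pim_01 to sna_pim_22. The frames of sna_pim_08 (positions 12669 to 18743, reverse strand), sna_pim_09 (18779 to 24205, reverse), sna_pim_10 (24217 to 52758, reverse) and sna_pim_20 (69766 to 90159, reverse) hold 1, 1, 6 and 4 ketosynthase motifs, the mark of modular polyketide synthases, which build the macrolide ring. At the edges of the region lie sna_pim_01 (1190 to 2563, reverse, 457 codons) and sna_pim_22 (91866 to 93992, reverse, running past the end). The mean over the 22 cluster features was -1.41 ± 0.42 (SD, n = 3) in wild type, -2.78 ± 0.71 in ΔsodF and -1.88 ± 0.81 in ΔahpCD at T1, and -2.28 ± 1.34 in wild type, -1.44 ± 1.08 in ΔsodF and -1.05 ± 0.69 in ΔahpCD at T2. Wild-type T2 was the widest group, with -0.95 in replicate 1, -3.64 in replicate 2 and -2.26 in replicate 3. Tile means were taken over the predicted frames of 20 genes and, for sna_pim_03 and sna_pim_04, which had no frame on their strand, over the span of their probes. They followed the named probes, with r across genes from 0.968 to 0.995 over the 11 contrasts, though genes are not independent replicates.

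**Figure D2:**
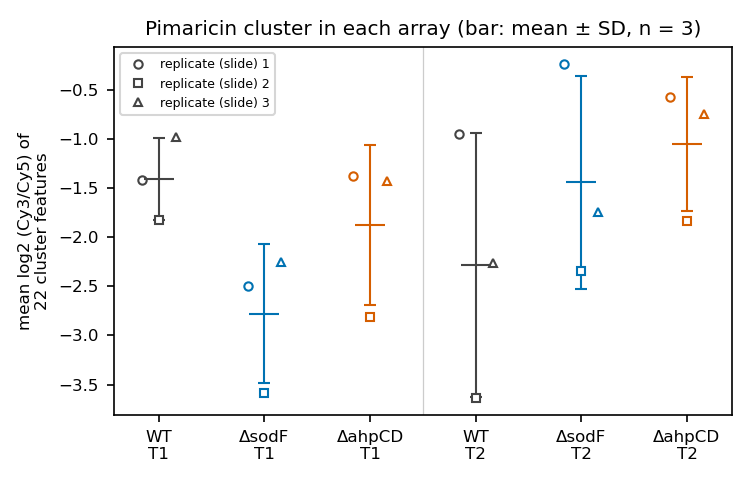
Mean normalised log2 ratio of the 22 pimaricin features, 1 point per array, with bars for the group mean ± SD (n = 3) and symbols for the replicate, which is also the slide. At T1 the ΔsodF mean of -2.78 is the lowest, and at T2 the wild-type arrays spread from -3.64 to -0.95.

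**Figure D3:**
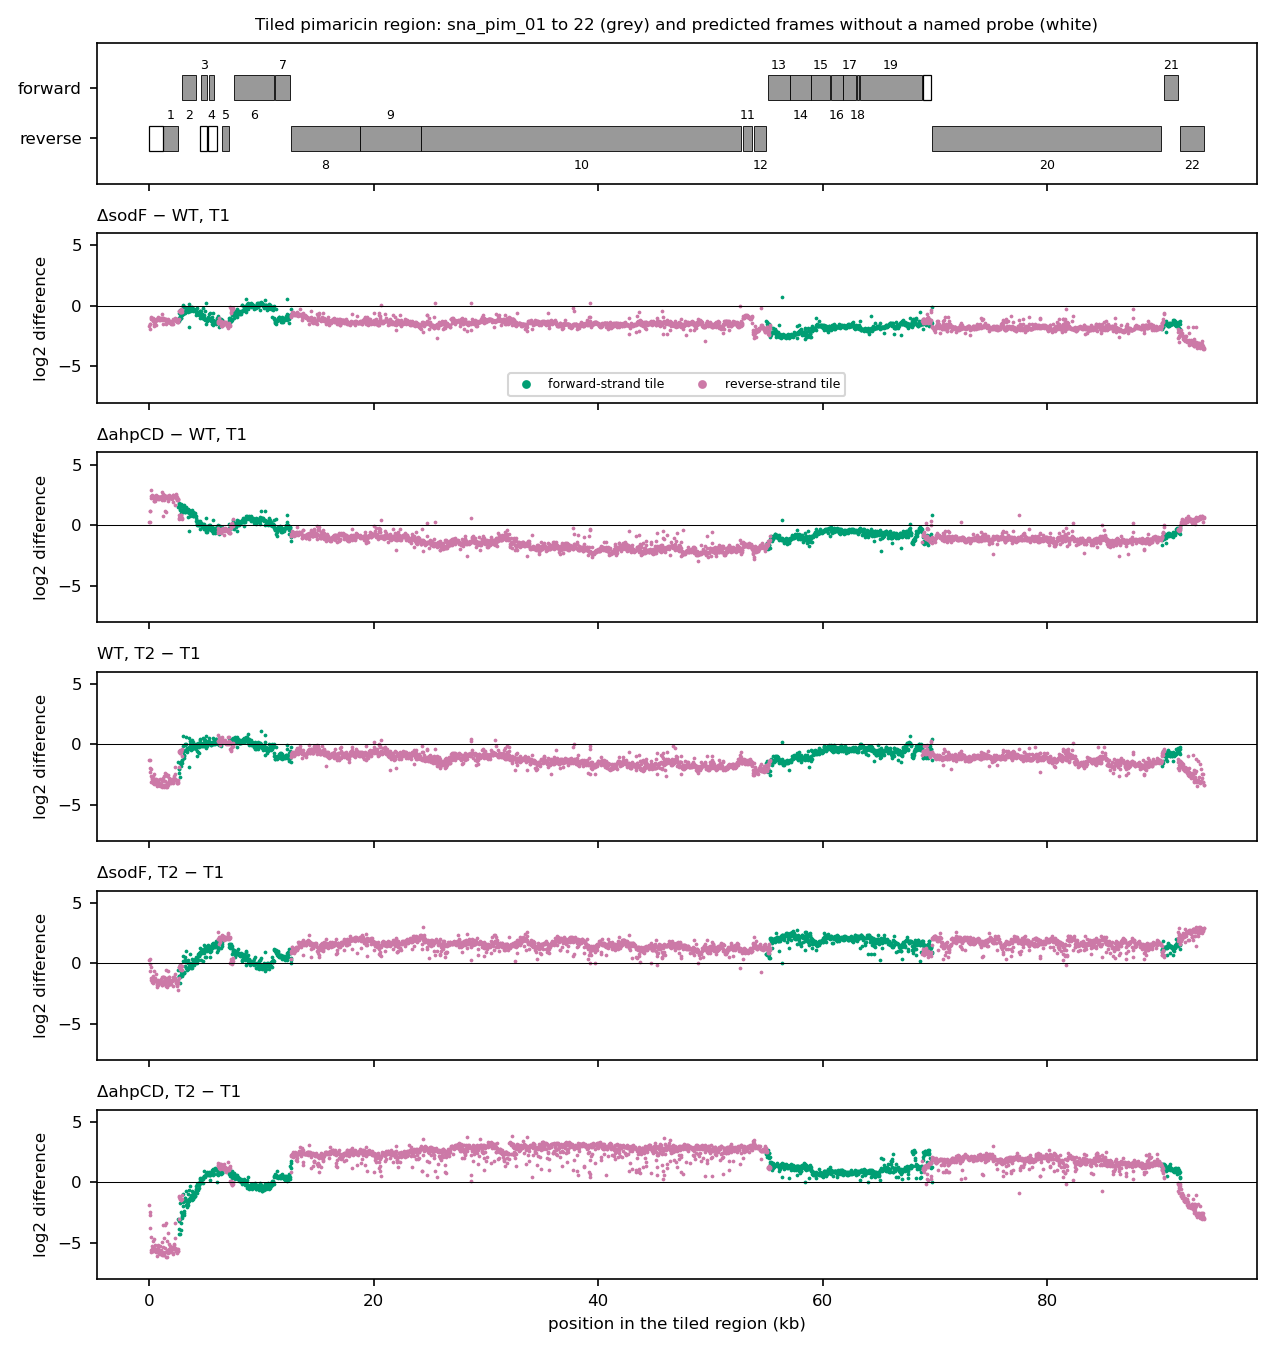
Top panel, predicted frames of the tiled region by strand, grey where they carry named probes. Lower panels, log2 difference of each tile between 2 groups (3 arrays each) against its position in kb, coloured by the strand the tile reads; the T1 difference of ΔsodF from wild type lies below 0 in the tile means of all 22 named genes.

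The first comparison asked how loss of sodF alters transcripts in late exponential phase. The median log2 difference of the 22 pimaricin features between ΔsodF and wild type was -1.40, with 21 below 0. Within the cluster, sna_pim_22 fell by 2.85 (SE 0.327, 7.22-fold, limma adjusted p = 0.000274), from -2.02 ± 0.36 to -4.87 ± 0.12 (SD, n = 3), and was lower on all 3 slides. Outside the cluster, SAV6663 rose by 6.05 (SE 0.418, adjusted p = 2.81e-06) and SAV1627 by 3.83 (SE 0.555, adjusted p = 0.00208), while SAV4354 fell by 4.29 (SE 0.839, adjusted p = 0.0181) and SAV4841 fell by 3.70 (SE 0.716, adjusted p = 0.0179). The phosphate features, named for the sensor kinase PhoR, the response regulator PhoP and PhoU, which act in phosphate control, had a median of -0.08.

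Of 4693 features tested at T1, 20 were higher and 30 lower in ΔsodF. With the slide as a block the counts were 144 and 80, and these held all 50. The pimaricin list lay below the other features by camera (adjusted p = 3.95e-13; adjusted p = 0.125 with an estimated correlation, and 0.046 with an estimated correlation and the block). Of its members 1 fell and 1 fell adjusted over the list alone; with the block 8 fell, 15 adjusted over the list alone, among them sna_pim_13 (-2.41, adjusted p = 0.539 without and 0.011 with the block) and sna_pim_14 (-2.22, 0.343 and 0.00278). The phosphate list had an adjusted p of 0.338 and a median of 0.03, 0.55 and 0.92 under quantile normalisation, Agilent's processed signals and normalisation with the tiles. Also with the block only, sna_sngR, a gamma-butyrolactone receptor gene, was lower (-1.19, adjusted p = 1 without and 0.013 with the block, though 0.03 with Agilent's processed signals) and sna_ipp higher (1.44, 0.958 and 0.00985). The cluster median stayed below 0 under every scaling and with any 1 array left out, from -1.77 with Cy3 alone to -0.26 with Agilent's processed signals. The share of called features that were higher was 40.0%, against 54.8% with quantile normalisation, 61.2% with loess within arrays, 63.0% with Cy3 alone, 79.4% with Agilent's processed signals and 88.6% with the tiles. The 50 calls became 32, 30 and 32 without wild-type replicate 1, wild-type replicate 3 and ΔsodF replicate 1. The calls of SAV4354 (adjusted p up to 0.096) and SAV4841 (up to 0.0919) ended without either of these wild-type arrays or without ΔsodF replicate 1 or 2, and that of SAV4354 also without ΔsodF replicate 3.

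At T2 the same strains differed in fewer features. The feature SAV1911 rose by 1.85 (adjusted p = 0.0118) in ΔsodF, on all 3 slides. The phosphate features lay higher in ΔsodF, with a median of 1.11 and 9 of 9 above 0, and the pimaricin features had a median of 0.83 with 20 of 22 above 0. For sna_pim_22 the difference was 1.89 (SE 0.327), positive on all 3 slides, with an adjusted p of 0.102 and of 0.000836 with the block.

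That was 1 call, upwards, among 4700 features (91 at an unadjusted p under 0.05); with the block there were 17 higher and 2 lower. The phosphate list shifted up (camera adjusted p = 5.64e-11, 0.0195 with an estimated correlation), with medians of 0.21 to 1.51 over all alternatives, though 0 of its members passed, over all features or adjusted over the list alone (with the block 0, and 8 of 9 adjusted over the list alone), with sna_phoP at 1.29, sna_phoU at 1.24 and sna_phoR at 1.11. The pimaricin list had an adjusted p of 5.05e-09 and of 0.129 with an estimated correlation, and 0 members rose (1 adjusted over the list alone, and 1 with the block either way). Its median was -0.01 with Agilent's processed signals and 0.14 without wild-type replicate 2. The SAV1911 call ended without any of the 3 wild-type arrays or ΔsodF replicate 3 (adjusted p up to 0.0754) and under several scalings. The count was 0 without wild-type replicate 2 or 3 or ΔsodF replicate 3 and 2 without ΔsodF replicate 1, and sna_pim_22 was called without wild-type replicate 1 (adjusted p = 0.0329).

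Loss of ahpCD was examined in the same way. At T1, SAV3232 and SAV3233 fell in ΔahpCD by 4.63 (SE 0.547, 24.7-fold, adjusted p = 0.00139) and fell by 4.38 (SE 0.482, adjusted p = 0.00117), while SAV3052 rose by 4.28 (SE 0.698, adjusted p = 0.0274) and SAV2733 by 2.92 (SE 0.412, adjusted p = 0.00748). The phosphate features were higher in ΔahpCD, with a median of 1.52 and 9 of 9 above 0. In the pimaricin cluster 16 of 22 features lay below 0 and the median was -0.61, while sna_pim_01 stood at 2.33 (SE 0.8).

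Of 4694 features 2 were higher and 2 lower; with the block 38 were higher and 9 lower, including all 4. The phosphate list shifted up (camera adjusted p = 2.34e-11; 0.0175 with an estimated correlation, but 0.0555 with an estimated correlation and the block), with medians from 0.85 to 2.32 over all alternatives. Of its members 0 rose over all features and 8 of 9 adjusted over the list alone; with the block these counts were 4 and 8. Over all features, the block brought calls of sna_phoR (1.69, adjusted p = 0.676 without and 0.0123 with the block), sna_phoU (1.63, 0.919 and 0.0477) and sna_pim_01 (0.919 and 0.00972). The pimaricin list had an adjusted p of 0.104 (0.0364 with the block, 0.659 with an estimated correlation), 0 members passed either way (with the block 1 rose, 2 adjusted over the list alone), and its median was 0.05 with Agilent's processed signals. The count of 4 was 2 without wild-type replicate 2 or ΔahpCD replicate 3 and 9 without ΔahpCD replicate 2. SAV3052 was not called without wild-type replicate 1 or 2 or ΔahpCD replicate 1 or 3 (adjusted p up to 0.248), nor SAV2733 without wild-type replicate 2 or ΔahpCD replicate 3 (up to 0.0765). The share of higher calls, 2 of 4, was 33.3% with quantile normalisation and 95.3% with the tiles.

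At T2, SAV3232 fell by 5.32 (SE 0.547, 40.0-fold, adjusted p = 0.000248) and SAV3233 fell by 5.50 (SE 0.482, 45.4-fold, adjusted p = 6.47e-05) in ΔahpCD. SAV3233 measured 0.40 ± 0.78 in wild type and -5.11 ± 0.20 in ΔahpCD (SD, n = 3). The pimaricin features had a median difference of 1.04 with 21 of 22 above 0, and the phosphate features had a median of 0.20 with 8 of 9 above 0.

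These 2 features were the calls among 4700 (50 at an unadjusted p under 0.05), and the block gave 1 higher and 2 lower. The pimaricin list lay above the other features (camera adjusted p = 1.29e-20, 0.0444 with an estimated correlation), although 0 of its members rose (with the block 0, and 14 adjusted over the list alone). Its median was -0.06 with Agilent's processed signals and 0.39 without wild-type replicate 2, the array with the lowest cluster mean of its group. Neither SAV3232 nor SAV3233 was called at T1 or T2 in a fit on the compared groups alone. For the phosphate list the adjusted p was 0.0636, and its median was -0.11 with loess within arrays, -0.07 with Cy3 alone, -0.65 with Agilent's processed signals, -1.13 with the tiles, -0.17 without wild-type replicate 2 and -0.04 without ΔahpCD replicate 1.

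The phase comparisons asked what changed between late exponential and early stationary growth within a strain. In wild type, SAV4265 rose by 5.13 (SE 0.468, 35.1-fold, adjusted p = 0.00011) and SAV6020 by 2.37 (SE 0.324, adjusted p = 0.00521), and SAV4363 fell by 3.13 (SE 0.379, adjusted p = 0.00189). In the pimaricin cluster sna_pim_22 fell by 2.30 (SE 0.327, adjusted p = 0.00597), lower at T2 on all 3 slides, and sna_pim_01 stood at -3.11 (SE 0.8, adjusted p = 0.435, and 0.000983 with the block). Of 9 features for hrdB of other species, which name the principal sigma factor, 0 were called without and 5 were higher at T2 with the block, such as sal_hrdB (1.34, adjusted p = 0.963 without and 0.0034 with the block) and san_hrdB (1.26, 0.821 and 0.00373). That list was chosen after the names were read, and its adjusted p with an estimated correlation was 0.0948.

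Of 4695 features 4 rose and 2 fell; with the block 52 rose and 25 fell. The pimaricin median was -0.67 with 19 of 22 below 0 (camera adjusted p = 6.1e-06, 0.228 with an estimated correlation; 1 member fell, 2 adjusted over the list alone, and 2 with the block either way), and the phosphate median -0.46 (0.00575, and 0.228 with an estimated correlation). Both directions depended on the settings: the pimaricin median was 0.07 with Agilent's processed signals and 0.10 without wild-type T2 replicate 2, and the phosphate median was 0.28 with Agilent's processed signals and 0.18 with the tiles. The count of 6 was 3 without T1 replicate 1 or T2 replicate 3, which also ended the call of sna_pim_22 (adjusted p up to 0.0581), as did 5 of the processing alternatives, and that of SAV6020 ended with Cy3 alone and with Agilent's processed signals. The share of higher calls was 66.7%, against 77.8% with loess within arrays, 33.3% with Cy3 alone and 94.3% with the tiles.

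In ΔsodF most pimaricin features lay higher at T2 than at T1. The median of the 22 features between T2 and T1 was 1.66 with 20 above 0, and sna_pim_22 rose by 2.44 (SE 0.327, 5.42-fold, adjusted p = 0.00176), on all 3 slides. SAV4265 rose by 7.24 (SE 0.468, 151-fold, adjusted p = 1.13e-06) and SAV2686 by 5.20 (SE 0.841, adjusted p = 0.00487). SAV6663, which had been high at T1, fell by 4.56 (SE 0.418, adjusted p = 5.8e-05) and SAV4912 fell by 3.58 (SE 0.58, adjusted p = 0.00487).

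Of 4693 features 36 rose and 18 fell; with the block 233 rose and 160 fell, all 54 among them. The pimaricin list had a camera adjusted p of 4.31e-08 and of 0.222 with an estimated correlation; 1 member rose and 9 rose adjusted over the list alone, and with the block 11 rose, or 15 adjusted over the list alone, among them sna_pim_05 (2.16, adjusted p = 0.177 without and 0.0011 with the block), and 1 fell. Also with the block, sna_sngA (2.19, 0.107 and 0.000763) and sna_sngR (1.24, 0.631 and 0.0089, though -0.17 with Agilent's processed signals) were called. The phosphate median was 0.53 (adjusted p = 0.00512, 0.222 with an estimated correlation; 0 members rose, and 1 with the block) but -0.07 with Agilent's processed signals and -0.46 with the tiles. The pimaricin median stayed above 0, at 0.47 with Agilent's processed signals, where the call of sna_pim_22 ended (adjusted p = 0.0552), as it did with Cy3 alone (0.232). The count of 54 was 23 and 29 without T1 replicates 1 and 3, and 30 and 26 without T2 replicates 1 and 3. Higher calls made up 66.7%, against 82.1% with median centring only, 34.4% with Cy3 alone, 42.3% with Agilent's processed signals and 29.3% with the tiles.

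In ΔahpCD the genes at both edges of the cluster fell between T1 and T2. The gene sna_pim_01 fell by 5.55 (SE 0.8, 46.8-fold, adjusted p = 0.00568), from 1.61 ± 0.98 to -3.94 ± 0.56 (SD, n = 3), and sna_pim_22 fell by 1.64 (SE 0.327, adjusted p = 0.047). Of all 22 features 18 lay above 0, with a median of 0.95. The phosphate features fell as a list, with a median of -1.84 and 8 of 9 below 0. Outside these lists, SAV4265 rose by 6.11 (SE 0.468, adjusted p = 1.11e-05) and SAV6020 by 2.75 (SE 0.324, adjusted p = 0.000871), and SAV4363 fell by 4.38 (SE 0.379, adjusted p = 2.79e-05) and SAV4362 fell by 4.31 (SE 0.667, adjusted p = 0.00789).

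Of 4695 features 3 rose and 14 fell; with the block 46 rose and 55 fell. The phosphate list had a camera adjusted p of 1.66e-15 and of 0.00591 with an estimated correlation, with medians of -2.81 to -1.26 over all alternatives. Of its members 0 fell over all features and 8 of 9 adjusted over the list alone, and with the block 8 either way. Over all features sna_phoR (-1.86) had an adjusted p of 0.186 without and 0.00391 with the block and sna_phoP (-2.02) of 0.492 and 0.0246, and sna_phoR was also called under several scalings, without slide 2 and without T1 replicate 2 (adjusted p = 0.0408). The pimaricin list had an adjusted p of 0.00156 and of 0.396 with an estimated correlation, and its median was 0.05 with Agilent's processed signals. Of its members 2 fell, also when adjusted over the list alone, and with the block sna_pim_11 (2.90, adjusted p = 0.744 without and 0.0481 with the block) and 1 other rose, with 16 rising and 4 falling when adjusted over the list alone. The count of 17 became 6 without T1 replicate 1 or 3, 7 without T2 replicate 1 or 2 and 8 without T2 replicate 3. Leaving out any of these 5 also ended the call of sna_pim_22 (adjusted p up to 0.304), and that of SAV4362 ended without T1 replicate 1 or 3 or T2 replicate 2 (up to 0.0741). The call of SAV6020 ended with Cy3 alone, Agilent's processed signals and the tiles. The share of higher calls was 17.6%, against 33.3% with median centring only, 28.6% with quantile normalisation, 32.1% with loess within arrays, 13.0% with Agilent's processed signals and 10.6% with the tiles.

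**Figure D4:**
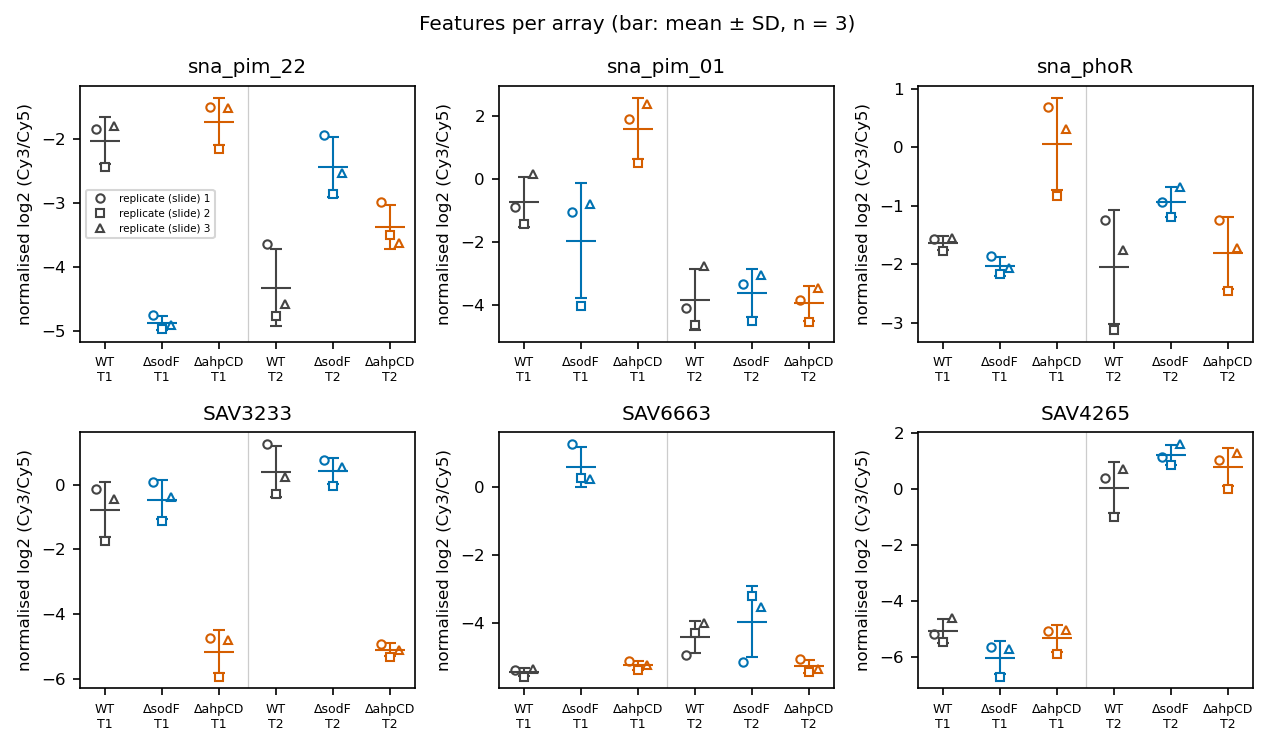
Normalised log2 ratio of 6 features on each array, with bars for the group mean ± SD (n = 3); symbols give the replicate, which is also the slide. SAV3233 is low in all 6 ΔahpCD arrays, SAV6663 is high in the 3 ΔsodF arrays of T1, and SAV4265 is higher at T2 in all strains.

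The mutants were also compared with each other. At T1, sna_pim_22 was lower in ΔsodF than in ΔahpCD by a log2 difference of -3.15 (SE 0.327, adjusted p = 7e-05), as were sna_pim_01 (-3.56, SE 0.8, adjusted p = 0.0464) and sna_phoR, a sensor kinase gene (-2.09, SE 0.454, adjusted p = 0.0386). The phosphate features lay lower in ΔsodF, with a median of -1.38 and 9 of 9 below 0, and the pimaricin median was -0.72 with 21 of 22 below 0. SAV6663 was higher in ΔsodF by 5.86 (SE 0.418, adjusted p = 4.32e-06) and SAV3233 by 4.68 (SE 0.482, adjusted p = 7e-05), and SAV4354 (-5.52, SE 0.839, adjusted p = 0.00232) and SAV4362 (-5.30, SE 0.667, adjusted p = 0.000542) were lower.

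Of 4692 features 20 were higher and 34 lower in ΔsodF; with the block 82 and 120. The phosphate list had a camera adjusted p of 5.7e-12 (0.0147 with an estimated correlation; 1 member fell, 8 adjusted over the list alone, and 8 with the block either way), and the pimaricin list 3.43e-08 (0.15 with an estimated correlation; 2 members fell either way, and with the block 4, or 12 adjusted over the list alone). With the block sna_sngR was also lower (-1.80, adjusted p = 0.523 without and 0.000635 with it). The count of 54 was 35 without ΔsodF replicate 1 and 34 without ΔahpCD replicate 1. The call of sna_pim_01 ended without ΔsodF replicate 1 or 2 or ΔahpCD replicate 1 or 3 (adjusted p up to 0.226) and that of sna_phoR without any of these or ΔsodF replicate 3 (up to 0.235), and both were lost under several other settings. Higher calls made up 37.0%, against 51.7% with Cy3 alone and 56.5% with the tiles.

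At T2, SAV3232 and SAV3233 were higher in ΔsodF than in ΔahpCD by 5.70 (SE 0.547, adjusted p = 0.000104) and 5.52 (SE 0.482, adjusted p = 6.18e-05). The phosphate median was 0.69 with 8 of 9 above 0, and the pimaricin median -0.33 with 18 of 22 below 0. In all, 3 of 4700 features were higher and 0 lower (61 at an unadjusted p under 0.05), and with the block 6 and 0. The phosphate list had a camera adjusted p of 6.38e-10 (0.0267 with an estimated correlation, 0.0509 with an estimated correlation and the block) and the pimaricin list 0.0102 (0.488 with an estimated correlation). No member of either passed, and with the block 7 phosphate features and 1 pimaricin feature were higher when adjusted over the list alone. The pimaricin median was 0.03 without ΔsodF replicate 2, and 5 features were called without ΔsodF replicate 1.

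Whether the change between phases differed between a mutant and wild type was tested as an interaction. For ΔsodF, sna_pim_22 was the only feature with a symbol that was called, at 4.74 (SE 0.462, adjusted p = 0.000255, positive on all 3 slides), from the fall in wild type and the rise in the mutant given above. The change in SAV4363 (3.65, SE 0.537, adjusted p = 0.00727) and SAV4350 (3.57, SE 0.506, adjusted p = 0.00727) was higher in ΔsodF, and that in SAV6663 (-5.60, SE 0.592, adjusted p = 0.000355) and SAV4913 (-4.24, SE 0.871, adjusted p = 0.05) was lower. All 22 pimaricin features lay above 0, with a median of 2.47, and 9 of 9 phosphate features, with a median of 1.03.

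Of 4693 features 10 were higher and 12 lower; with the block 67 and 56. The pimaricin list had a camera adjusted p of 5.69e-20 (0.0423 with an estimated correlation). Of its members 1 was higher, also when adjusted over the list alone, and with the block 8, or 18 adjusted over the list alone. Among these were sna_pim_13 (3.58, adjusted p = 0.712 without and 0.0137 with the block) and sna_pim_14 (3.16, 0.545 and 0.00529). That of the phosphate list was 8.03e-07 (0.0423 with an estimated correlation, 0.0598 with an estimated correlation and the block), with 0 members called and 3 higher with the block adjusted over the list alone. The pimaricin median was 0.13 with Agilent's processed signals, and the phosphate median was -0.38 there and -0.66 with the tiles. The count of 22 was 11 without wild-type T1 replicate 1 or T2 replicate 1, 6, 14 and 8 without ΔsodF T1 replicates 1, 2 and 3, and 10 and 9 without ΔsodF T2 replicates 1 and 3. SAV4913 was past the threshold by less than the rounding of its adjusted p and was lost without any of 11 of the 12 arrays, wild-type T2 replicate 2 being the other (adjusted p up to 0.164). The call of SAV4350 ended under quantile normalisation, Cy3 alone and Agilent's processed signals, and that of SAV4363 under quantile normalisation. Higher calls made up 45.5%, against 71.4% with median centring only, 29.2% with Cy3 alone, 13.7% with Agilent's processed signals and 8.82% with the tiles.

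For ΔahpCD the median interaction of the 22 pimaricin features was 1.35 with 19 above 0, and that of the 9 phosphate features -1.08 with 9 below 0. No single feature of 4694 was called by limma (68 at an unadjusted p under 0.05), and 4 were lower with the block. The phosphate list had a camera adjusted p of 1.62e-08 (0.0463 with an estimated correlation) and stayed below 0 under every alternative, from -3.25 to -0.73. The pimaricin list had 2.16e-12 (0.0702 with an estimated correlation, 0.0422 with an estimated correlation and the block), and its median was -0.23 with Agilent's processed signals. No member of either list passed, while with the block and adjusted over the list alone 14 pimaricin features were higher and 2 lower and 6 phosphate features lower. A single feature was called without ΔahpCD T1 replicate 2 or wild-type T2 replicate 1.

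Both mutants were set against the same wild-type arrays. No feature was called in both at T1 or at T2; with the block 11 rose in both at T1, with 0 simulated and 1.17 from independent lists, 6 moved in opposite directions, and 1 rose in both at T2, with 0 simulated and 0.00362 from independent lists. Simulated groups were unchanged and shared the wild-type arrays, and independent lists share none, so neither value alone is the chance of these overlaps. Across features, log2 differences from wild type correlated with r 0.354 at T1 and 0.563 at T2, against 0.502 in 100 simulations of unchanged groups that shared the wild-type arrays. The covariance was 0.0974 at T1 and 0.0661 at T2, against 0.0434 simulated. The simulations drew arrays independently, with the spread left after the slide block. Over features with no missing value the covariance was 0.0913 at T1 and 0.0625 at T2, against 0.0528 and 0.0575 expected from the spread of the differences within slides, a comparison added after the values were seen. With 3 wild-type arrays per phase the controls were too few to split, so part of any excess may come from sharing them.

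Scaling moved all features together where the tiles took part in the normalisation. The median over all features then became 0.36 and -0.26 for ΔsodF against wild type at T1 and T2, 0.25 and -0.39 for ΔahpCD against wild type, and 0.28, -0.34 and -0.35 for T2 against T1 in wild type, ΔsodF and ΔahpCD. It became 0.13 for ΔsodF against ΔahpCD at T2, and -0.63 and -0.62 for the interactions of ΔsodF and ΔahpCD. With Agilent's processed signals it was 0.14 for the interaction of ΔahpCD.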

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

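Chosen only after the result was seen were the tests of the genomic DNA channel, of the processing and of the loess between arrays, of the exchange with the ΔahpCD array, of an additive slide effect, of stringency itself and of the RNA samples alone, of the slope for the ΔsodF exchange, the features and rule of its position and the rule for the partly matching probes, and the choice of stretches without named probes and the adjustment over them.

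The change between phases differed between ΔsodF and wild type in 22 features, by the interaction of strain and phase. For sna_pim_22 it differed by 4.74, because this gene fell by 2.30 in wild type and rose by 2.44 in ΔsodF, and the difference was positive on all 3 slides. The others given in the report were SAV6663 (-5.60), SAV4363 (3.65), SAV4350 (3.57) and SAV4913 (-4.24), the last lost without any of 11 of the 12 arrays (adjusted p up to 0.164). The median difference of the pimaricin list was 2.47, though far smaller with Agilent's processed signals. That of the phosphate list was 1.03, but -0.38 with Agilent's processed signals and -0.66 with the tiles in the normalisation. For ΔahpCD the phosphate median differed by -1.08, below 0 under every alternative.

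Splits of the same 12 arrays, with strain labels exchanged within each phase, were drawn at random to make 100 with the real one. For the ΔsodF interaction 4 of the 100, the real one included, gave at least 22 calls, and the highest other split gave 41. Most of those splits leave both arrays of some slide on the same side. In that draw, 16 other splits part all pairs of the same slide, like the real one. Of these 1 gave at least as many, 29, so chance in the grouping was not excluded once slides were taken into account. With the slide as a block the real count was 123. For ΔahpCD the real count was 0, which any split reaches (100 of 100), so its splits say nothing on chance; the highest other split called 1122 features, which points to a structure of the samples, while among splits that part all pairs the highest called 2.

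Tiles outside the frames, probe spans and probes of the 22 named genes, which no comparison of the report used, also changed, in 20 of 187 tests, which fell in 7 of 17 stretches. Of each of the 7 the test with the smallest adjusted p is given. In ΔahpCD between T1 and T2, the stretch between sna_pim_01 and sna_pim_02 changed by -3.32 on the forward strand (adjusted p = 7.41e-05) and by -1.92 on the reverse strand (adjusted p = 0.000172), and the first frame with no named probe by -5.30 (adjusted p = 0.000395). The reverse strand between sna_pim_21 and sna_pim_22 changed with a ΔsodF interaction of 4.11 (adjusted p = 0.000583). Smaller or less certain signals were -0.84 between sna_pim_05 and sna_pim_06 on the reverse strand in ΔsodF against wild type at T1 (adjusted p = 0.0354), 1.55 between sna_pim_04 and sna_pim_05 on the forward strand in ΔsodF between phases (adjusted p = 0.0354), and 4.05 over 4 tiles between sna_pim_12 and sna_pim_13 on the forward strand in the ΔahpCD interaction (adjusted p = 0.0354). As sna_pim_04 had no predicted frame on its strand, its gene may reach past its probes into the stretch with 1.55. On the opposite strand, frames were predicted over the probes of sna_pim_03 (4501 to 5145) and of sna_pim_04 (5275 to 6075). Which strand holds these genes was not examined.

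The lower pimaricin transcripts of ΔsodF at T1 were weighed first. The genomic DNA channel argues against a difference in the reference, since the Cy5 signal of the tiles differed by -0.094 on average and by -0.24, 0.05 and -0.10 on the slides, far less than the median of -1.40. A harvest of ΔsodF at an earlier point of growth than wild type needs a negative slope on the ΔahpCD phase difference. Over 97 features the slope was 0.306 (0.297, 0.283 and 0.338 on the slides). However, of features called between phases in both mutants with the block, 21 moved the same way and 21 in opposite ways. The ΔahpCD phase difference may therefore not order growth in ΔsodF. The slope does not decide, and an earlier or a later harvest stays open. The loess between arrays is argued against as the whole cause by cluster medians of -1.39, -1.36 and -1.50 without it, with quantile normalisation and with loess within arrays. The processing as a whole may account for part of the size. The median was -0.26 with Agilent's processed signals, which change several steps at once and are dye-normalised over spots that include the tiles. It was -0.57 with the tiles in the normalisation, which take the cluster itself as reference. The loss of sodF itself stays open as the biological explanation and was not separated from these.

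The second pattern was the spread of wild-type T2, where replicate 1 had the highest cluster mean, -0.95, against -2.26 and -3.64, which lie as far from each other. An exchange with the ΔahpCD array of its slide is argued against by SAV3232 and SAV3233, at 1.27 on that array, 0.38 on the other wild-type arrays and -4.74 in ΔahpCD. A wild-type culture at a much earlier point of growth is argued against by a phase slope of 0.839, near those of slides 2 and 3 (0.643 and 0.862). That slope rests on 19 features chosen for moving the same way in both mutants, so a small shift in harvest stays open. An exchange with the ΔsodF array is argued against by a slope of 0.17 of the ΔsodF difference of slide 1 on that of slides 2 and 3 over 74 features (bootstrap 95% interval 0.065 to 0.276, though features are not independent), where an exchange needs a negative one; a position between ΔahpCD (0) and ΔsodF (1) over 4 features was too variable to decide, at 0.18, with the other wild-type arrays at 0.395 and -0.255 and the ΔsodF array of that slide at 0.046. An additive effect of slide 1 on the cluster needs about the same difference in every group. The wild-type difference of slide 1 from slides 2 and 3 was 2.001, against -0.01, 0.42, 0.74, 1.81 and 0.72 in the other groups (mean 0.73, SD 0.67). The wild-type value lay above that mean but within 2 SD of it, the range set for an additive effect, and near the 1.81 of ΔsodF at T2. The other groups were too unlike each other for this comparison to decide, so a slide effect stays open. No biological explanation beyond the harvest point was tested.

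The third pattern was slide 2. The ratio of matched tiles to mismatch copies in Cy5 was highest there in 6 of 6 groups. A difference in hybridisation or washing stringency could produce this, but the ratio is the pattern itself, so testing stringency by it could not decide. The median Cy5 ratio difference between slide 2 and the other slides was 0.625 (0.53 to 0.851). Every array received wild-type genomic DNA in that channel, so RNA samples could not produce this ratio and the outcome was fixed beforehand. It does not say whether RNA or cultures add to the difference of slide 2 in the ratios of Cy3 over Cy5. Stringency acting on partly matching probes needs the Cy5 difference of slide 2 to rise clearly with matching bases. No such rise was seen over 169 probes with 42 to 59 matching bases. Spearman's rho across probes was -0.079 (two-sided permutation p = 0.31 over 100000 permutations, bootstrap 95% interval -0.241 to 0.088), and Pearson's r was -0.118. Other Cy5 values, read afterwards and not tested, went the way of higher stringency on slide 2. Named probes over their mismatch copies had median log2 ratios of 3.656 to 5.944 there, against at most 3.531 on slides 1 and 3. The median log2 Cy5 of SAV probes was lowest there in every group (6.694 to 6.825). In ΔsodF at T1 that was only 6.71 against 6.713. Tiles were lowest there in no group (14.07 to 14.43), so stringency stays open. No biological explanation was tested. The slides held all 6 groups, but a batch of cultures with the same replicate number coincides with the slide.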

How the results depend on the processing

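The alternatives with the tiles in the normalisation, the normalisation and the filter on probes of strong Cy5 signal, the mismatch copies kept as features, the fit without slide 2 and the covariance expected from differences within slides were chosen after seeing the data, and the others before.

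Of 61 results for named features, 61 kept direction and call with the filter on Cy5 signal and with the mismatch copies as features, 60 with normexp in Cy3 only, 58 with normalisation on probes of strong Cy5 signal, 57 with no background correction, no filter or the brightest probe and 56 with median centring only. It was 52 with quantile normalisation or the stricter filter, 51 with loess within arrays and 48 with Agilent's processed signals or the tiles. Without slide 2 it was 47, with Cy3 alone 45, with the block 41 and in fits on the groups of a contrast alone 40. The other 20 became called with the block. Each of these 20 was given in the report together with its call under the block, so that outcome was fixed by the choice of features. The exceptions that reversed were sna_sngR with Agilent's processed signals, 0.032 in ΔsodF against wild type at T1 and -0.172 between phases in ΔsodF; neither was called without the block. The calls of sna_pim_22 in ΔsodF against wild type at T1, in ΔsodF against ΔahpCD at T1 and in the ΔsodF interaction, and those of SAV6663, held under every alternative run for named features, which left out the trended robust variance and the 2-fold threshold. The cause was not tested for any result here unless a cause is given.

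Counts below follow the order of the report. Median centring only gave 32 calls for ΔsodF against wild type at T1, 0 at T2, 6 for the phases of ΔahpCD and 7 for the ΔsodF interaction. Quantile normalisation gave 31 for ΔsodF at T1, 28 for the phases of ΔsodF, 7 for those of ΔahpCD, 29 for ΔsodF against ΔahpCD at T1 and 2 for the ΔsodF interaction. Loess within arrays gave 116 and 0 for ΔsodF at T1 and T2, 18, 94 and 28 for the phases of wild type, ΔsodF and ΔahpCD, 83 for ΔsodF against ΔahpCD at T1 and 49 for the ΔsodF interaction. Cy3 alone gave 81 for ΔsodF at T1, 10 for ΔahpCD at T1, 96 for the phases of ΔsodF, 89 for ΔsodF against ΔahpCD at T1, 48 for the ΔsodF interaction and 3 for that of ΔahpCD. Agilent's processed signals gave 165 and 0 for ΔsodF at T1 and T2 and 51 for its interaction, which was 14 with no background correction and 14 with no filter.

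With Cy3 well above background on 15 of 18 arrays, where fewer features were tested, the counts were 146 and 3 for ΔsodF at T1 and T2, 10 for ΔahpCD at T1, 14, 147 and 49 for the phases of wild type, ΔsodF and ΔahpCD, 141 for ΔsodF against ΔahpCD at T1 and 72 for the ΔsodF interaction. The brightest probe gave 2 for ΔsodF at T2, normalisation on probes with strong Cy5 signal gave 0 there, and the trended robust variance gave 9 for the phases of ΔahpCD. With the tiles in the normalisation the counts were 273 and 2 for ΔsodF, 64 and 4 for ΔahpCD, 53, 92 and 85 for the phases, 85 for ΔsodF against ΔahpCD at T1, and 136 and 370 for the interactions of ΔsodF and ΔahpCD.

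The slide as a block, which takes out the difference between slides, gave 224 and 19 for ΔsodF, 47 for ΔahpCD at T1, 77, 393 and 101 for the phases, 202 and 6 for ΔsodF against ΔahpCD, and 123 and 4 for the interactions; the mutants then shared 11 calls upwards at T1 and 1 at T2. Without slide 2 and its 6 arrays the counts were 117 and 0 for ΔsodF, 46 for ΔahpCD at T1, 127, 374 and 34 for the phases, 159 for ΔsodF against ΔahpCD at T1 and 35 for the ΔsodF interaction. Fits on the groups of a contrast alone, which have fewer samples for the variance, gave 0 for ΔsodF at T2, 0 and 0 for ΔahpCD at T1 and T2, 0, 29 and 1 for the phases, 23 for ΔsodF against ΔahpCD at T1 and 4 for the ΔsodF interaction; counts of 0 are by limma.

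With an estimated correlation, which widens the test of a list whose members move together, the pimaricin list had an adjusted p of 0.125 and 0.129 for ΔsodF at T1 and T2, 0.228, 0.222 and 0.396 for the phases, 0.15 and 0.488 for ΔsodF against ΔahpCD and 0.0702 for the ΔahpCD interaction, and the phosphate list had 0.228 and 0.222 for the phases of wild type and ΔsodF. With the block the pimaricin list for ΔahpCD at T1 had an adjusted p of 0.0364.

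With single arrays left out, the counts ran from 30 to 50 and 0 to 2 for ΔsodF at T1 and T2, 2 to 9 and 2 to 3 for ΔahpCD, 3 to 7, 23 to 49 and 6 to 25 for the phases, 34 to 59 and 2 to 5 for ΔsodF against ΔahpCD, and 6 to 21 and 0 to 1 for the interactions. The arrays that moved a count by over 1.5 times are named with it in the report.

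Signal over background limited the SAV probes: their median Cy3 was 90.3 to 113 over a background of 43.5 to 46.5, and 4493 of 7602 SAV features passed the filter and were tested.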

Other observations

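The test of the locus of SAV3232 and SAV3233 and the lists of this part were chosen after the names or values were seen, whereas the test of neighbouring identifiers was set before its result.

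Among lists added after the probe names were read, 9 hrdB features of other species had a median of 1.09 between phases in wild type, with 8 of 9 above 0 (camera adjusted p = 1.55e-07, 0.0948 with an estimated correlation, 0.0858 with the block as well). The 3 features named sng had a median of -0.86 in ΔsodF against wild type at T1 (adjusted p = 0.00557, 0.112 with an estimated correlation) and of -1.28 in ΔsodF against ΔahpCD at T1 (0.000211 and 0.0569, or 0.026 with an estimated correlation and the block). The 4 features kora, rep, spdA and spdb2, names of genes for plasmid replication and transfer, had a median of 0.64 in ΔsodF against ΔahpCD at T1 with 4 of 4 above 0 (0.000211 and 0.0333, but 0.192 with an estimated correlation and the block). The 95 features of other polyene clusters had medians of 0.05 in ΔahpCD against wild type at T2, 0.13 in the ΔsodF interaction and 0.13 in that of ΔahpCD, with an adjusted p of 0.0325, 0.0462 and 0.0276 with an estimated correlation, and of 0.105, 0.0587 and 0.112 with an estimated correlation and the block. For the 8 lysA features the lowest adjusted p with an estimated correlation was 0.306, at a median of -0.30 between phases in ΔsodF. Directions of these 5 lists were not examined under the scalings.

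SAV3232 and SAV3233 may lie in or next to the locus deleted in ΔahpCD. These 2 features were called lower in ΔahpCD than in wild type and than in ΔsodF at both phases, with mean differences from wild type of -4.98 and -4.94. They were the only calls against wild type at T2, so no other feature could have met these conditions. That no others did is therefore no separate support. The files do not say what the probes target, and a regulated pair of genes would look the same.

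Features with consecutive SAV numbers were called together more often than permuted ones, as co-transcribed neighbours could be: with SAV3232 and SAV3233 left out, pairs called the same way numbered 28, summed over the 9 comparisons of groups so that a pair can count more than once, against a mean of 0.549 and a highest of 9 in 10000 permutations of the calls over 2661 neighbouring pairs (one-sided permutation p = 1e-04, the smallest they can give). Whether neighbours lie side by side in natalensis was not examined.

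Each comparison of 3 arrays against 3 has 10 splits, too few for a share under 0.05, and 1 of 10, the real split, gave as many calls in each. The real counts and the highest of the other splits were 50 and 1 for ΔsodF against wild type at T1, 1 and 0 at T2, 4 and 0 for ΔahpCD at T1, 2 and 1 at T2, 6 and 0 for the phases of wild type, 54 and 0 for those of ΔsodF, 17 and 0 for those of ΔahpCD, 54 and 0 for ΔsodF against ΔahpCD at T1, and 3 and 1 at T2.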
